A study of Oryza sativa with 16 samples.

How the data were processed

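RNA of rice pericarps was measured on 16 arrays of an Agilent rice design with 45151 spots per array. Each array held a line labelled with Cy5 beside the cultivar Koshihikari of the same stage labelled with Cy3, with 400 ng of total RNA labelled per sample per the labels. There were 8 lines, each with 1 array at 7 and 1 array at 14 days after heading. The lines were near-isogenic lines (NIL) named BBA type, BAB type and ABB type, the Black rice NIL, the Red rice NIL, the line Tokei-1284 (with a space for the hyphen in the labels), and both reciprocal F1 of the Black and Red rice NIL. The titles give Tokei-1284 the genotype Rc/rd and the Red rice NIL Rc/Rd. The labels do not say whether the samples came from separate plants, so the p values measure only the spread between these samples. The arrays lay on 5 slides scanned on 4 days. The dyes were never swapped, so a dye effect of a probe is not removed from a comparison with Koshihikari, and lower bounds are open to it as well.

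The mean signals and local backgrounds of the deposited scanner files are in raw intensity, and their processed signals are intensity after background subtraction and dye normalization by Agilent Feature Extraction 10.5.1.1, per the file headers. The log ratios in the deposited scanner files are log10 of Cy5 over Cy3. The values deposited by the authors in the series table are in log2. Regressed on the scanner log ratio, it had slopes of 3.318 to 3.326 and r of 0.991 to 0.9999 over 42124 spots on each array, which gives its log base and its direction, the line over Koshihikari. Its column medians ran from -0.113 to 0.060, and the further normalization behind it is not stated.

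Of the spots, 1417 were controls. The comparisons used the 42105 spots (41889 probes) that carry a locus of the Rice Annotation Project (RAP), whose ID gives the chromosome after "Os"; no genome build or coordinates are in the files. Left out were 1020 spots for microRNA precursors and 609 other spots without such a locus. No spot was saturated. The median signal of an array ran from 165 to 483 in Cy3 and from 296 to 1036 in Cy5, and 72.7% to 82.8% of the spots lay well above background in a channel. The number of arrays limits the precision.

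Mean signals were corrected for the background median with normexp (offset 50) and normalized with loess within each array (span 0.3) in limma 3.58.1 under R 4.3.3, with the data.table package in version 1.17.8. Spots marked as outliers by the scanner software were set to missing, which touched 155 probes, and spots of a probe were averaged. Probes well above background in at least 1 channel on at least 2 arrays were kept (36370), and each gene is its brightest kept probe. This left 25213 of the 29689 loci. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9 and numpy 2.4.6.

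The log2 ratio was fitted in limma with a term per line and a centred stage term, with 7 residual degrees of freedom. The spread is thus the variation of a line's ratio between stages beyond the change common to all lines, and a line's value is the mean over both stages (n = 2 arrays). Koshihikari is the control on each array, and its own spread between plants is not in the error. Each line was tested against Koshihikari, 8 differences between lines were tested, and an F-test asked for any difference between the 8 lines. The change from 7 to 14 days was tested on log2 Cy5 intensity after Aquantile normalization between arrays with line as block, and on the ratio to Koshihikari. P values were adjusted by Benjamini-Hochberg over all genes within a comparison, and a gene below 0.05 is called. All tests of genes and lists are two-sided. Errors printed with ± are standard errors of this fit.

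It was planned on the premise that the Koshihikari reference drops out of a difference between lines. In the data this held only within a scan day, since the Koshihikari RNA differed between scan days. Many differences between lines are therefore given with the difference in Cy5 alone, an alternative chosen after the data were seen. Those given without it are open to the Koshihikari difference. The Cy5 values were normalized by way of the mean of both channels, so Koshihikari still enters them through the normalization. A fold is given as "at least" where one side lay at background on every array, and is then computed against the lowest intensity that was well above background on each array. For a difference between lines such a fold is one of Cy5 intensity, not of the ratio, and can exceed that of the ratio.

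The following lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The 28 lists were phenylpropanoid core, early flavonoid, late flavonoid, pigment regulators, flavone and flavonol branch, lignin branch, shikimate and aromatic amino acid, glutathione S-transferase, MATE transporter, UDP-glycosyltransferase, peroxidase, laccase, photosynthesis, chlorophyll and carotenoid synthesis, endosperm storage protein, endosperm starch synthesis, embryo and aleurone, abscisic acid, jasmonate, pathogenesis-related, heat shock protein, ribosomal protein, histone and cell cycle, cell wall, lipid transfer and cuticle, sugar transport and cleavage, MYB factor, and bHLH factor. The red pericarp regulator Rc (Os07g0211500) is not on the array. One listed lignin gene, Os04g0612700, was dropped because the array annotates it as a mannitol dehydrogenase. Lists were tested with camera at a preset correlation of 0.01 and at an estimated one, adjusted over the lists within a comparison.

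Every member of the first 5 lists could be named. Beyond these, the genes named are the 8 with the largest rise and the 8 with the largest fall per comparison among described, called genes of 1 sign at both stages, and the 4 called members with the largest change per other list with an adjusted camera p under 0.05. Genes named outside this rule are marked as chosen after their values were seen. Called genes were also counted in windows of 25 tested genes along each chromosome by a one-sided hypergeometric test, which is descriptive because neighbours are not independent.

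The fit per gene was tested on simulated data with 50 genes changed at each of several folds. The data were independent normal noise with the fitted spread of each gene. Normalization, filter and choice of probe were not run on them, and they held no difference between slides or scan days. The counts of unchanged genes called therefore do not cover such differences. For a line against Koshihikari it called 20 of 50 at 1.5-fold, 40 at 2-fold, 48 at 4-fold and 50 at 16-fold, with 13 unchanged genes called. For a difference between lines it called 6, 27, 44 and 47, with 10 unchanged genes called. Alternatives tried were no background subtraction, the scanner log ratios, the value table of the authors, median centring in place of loess, no filter, no stage term, the mean over probes, each array left out in turn, each line minus the mean of the other lines, and for stage no line block and each line left out. Leaving out either array of a line gives the same fit for comparisons that do not use that line. The 16 leave-outs are thus not 16 separate checks of a call. Slide as a random block was planned but gave no values, since each slide holds whole lines. After the data were seen, Cy5 alone, both BBA arrays left out, and each scan day with more than 1 line by itself were added.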

Results

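The data are 16 arrays of rice pericarp, 1 per line at 7 and at 14 days after heading, each holding 1 of 8 lines beside Koshihikari, a white-grained cultivar. The series asks how genes of the phenylpropanoid pathway, which supplies the flavonoid pigments, are expressed in black and red pericarps. Black rice owes its colour to anthocyanins and red rice to proanthocyanidins. A value for a line is its mean log2 ratio to Koshihikari over both stages (n = 2 arrays), and its error pools the spread over all 16 arrays. Of 25213 genes tested, 1266 differed between the 8 lines by the F-test in limma, and leaving out 1 array gave 164 to 1648. All 16 arrays moved that count, and those that moved it most were the 14-day Black array (164 without it), the 7-day Tokei-1284 array (191) and the 14-day Red array (302). With median centring in place of loess the count per line against Koshihikari ran from 2531 to 12425, and the median of all genes moved to 0.140 in Black, 0.116 in Red, 0.109 in BAB and 0.100 in BBA. As each line minus the mean of the other 7 lines it ran from 0 to 2600. Median signals were 165 to 483 in Cy3 and 296 to 1036 in Cy5.

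The Koshihikari RNA was not the same on all arrays. Between arrays of the same stage and scan day its intensities had r of 0.996 to 0.999 across genes (14 pairs), and between scan days 0.920 to 0.985 (42 pairs); genes are not independent replicates. The 8 genes lowest in Black against Red, nearly all heat-shock genes, had in Koshihikari a mean log2 intensity of 7.60 to 7.72 on the BBA slide, 9.58 to 10.49 on the arrays of BAB, ABB, Tokei-1284 and Red, 13.8 to 14.7 on the Black arrays and 14.0 to 14.2 on the F1 arrays. Their choice by the ratio favours a high Koshihikari signal on the Black and a low one on the Red arrays. Over the whole heat-shock list, the median deviation of Koshihikari from its mean over all arrays ran only from -0.15 to 0.17. The lowest r between log ratios of different lines was -0.315, over all probes, between Black at 14 days and Tokei-1284 at 7 days.

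**Figure D1:**
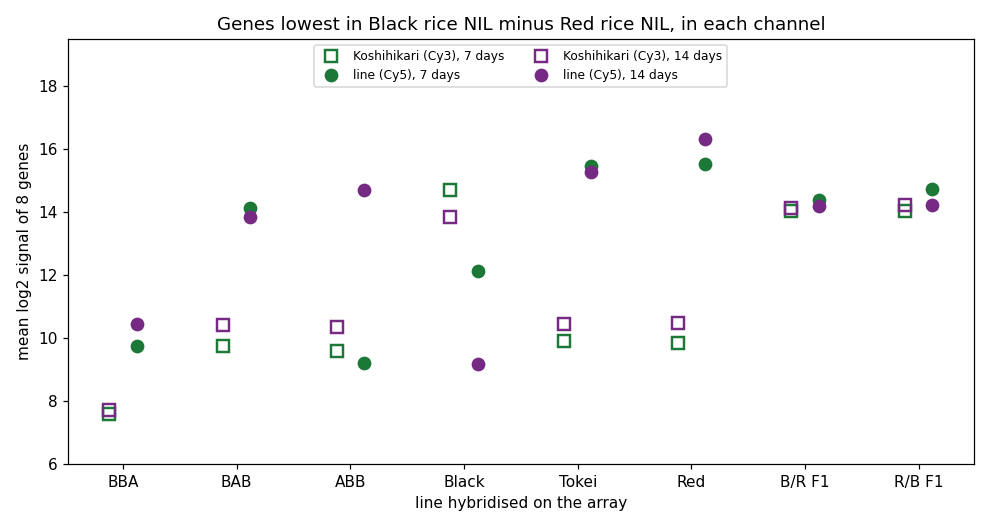
Mean log2 signal (vertical axis) of the 8 genes lowest in Black against Red, by the line on the array (horizontal axis), with open squares for Koshihikari and filled circles for the line and a colour per stage. The squares lie at 7.60 to 7.72 on the BBA arrays and at 13.8 to 14.7 on the Black arrays.

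In the Black rice NIL genes at several steps of the flavonoid pathway rose. Leucoanthocyanidin dioxygenase (Os01g0372500), which makes anthocyanidins, was 454-fold higher than in Koshihikari (log2 8.83 ± 0.71, adjusted p = 0.00132). Chalcone synthase (Os11g0530600), the entry enzyme of flavonoid synthesis, was 214-fold higher (7.74 ± 0.91, adjusted p = 0.00634), and a second chalcone synthase (Os07g0214900) 6.30-fold. Flavonoid 3'-monooxygenase (Os10g0320100) rose 141-fold, flavanone 3-hydroxylase (Os04g0662600) 35.8-fold, dihydroflavonol reductase (Os01g0633500, annotated as reductase A1) 83.7-fold, and the flavonoid glucosyltransferase Os06g0192100, whose kind stabilises anthocyanidins, 10.2-fold. Of the regulators, the bHLH gene Os04g0557500, listed as the black-pericarp regulator Kala4, rose 22.6-fold (4.50 ± 0.48, adjusted p = 0.00466), the WD40 gene Os02g0682500 4.29-fold and the MYB gene Os03g0410000 1.59-fold. The 4-coumarate-CoA ligase Os02g0697400 rose 5.82-fold, and the transporter Os01g0279400 42.1-fold. Log2 ratios differed between stages: Os11g0530600 was at 5.96 at 7 and 9.52 at 14 days, and Os04g0662600 at 2.91 and 7.41.

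By list, 4 of 9 early flavonoid genes rose in Black (7 adjusted over the list alone), as did 3 of 9 late flavonoid genes (4), 3 of 4 pigment regulators (3) and 1 of 18 phenylpropanoid core genes (3, with 1 lower). These counts rest on 1 probe per gene. For the phenylalanine ammonia-lyase Os04g0518100 that probe was at 0.35 in Black, 0.15 in Tokei-1284, 0.45 in Red, 0.66 in the Black/Red and 0.83 in the Red/Black F1, while a second one, nearly as bright, was at 1.87, 2.83, 3.41, 3.97 and 4.16. For chalcone synthase Os11g0530600, other probes nearly as bright as the one used were at 7.64 and 7.60 in Black, and a dimmer one was at 3.24. Camera gave the early list an adjusted p of 1.4e-06 (adjusted p = 0.391 with an estimated correlation), and no list call in any comparison held with an estimated correlation. Leucoanthocyanidin reductase (Os03g0259400, 0.14) did not pass. The 3 chalcone isomerase genes did not pass over all genes, but were higher at both stages. At 7 and 14 days Os03g0819600 was at 0.55 and 1.41, Os11g0116300 at 0.94 and 3.18 and Os12g0115700 at 1.26 and 3.21. Photosynthesis genes fell: 20 of 60 were lower (46 adjusted over the list alone), with a median of -0.79 (camera adjusted p = 3.95e-22; adjusted p = 0.391 with an estimated correlation). Examples are a chlorophyll a-b binding protein (Os01g0720500, -1.53 ± 0.31) and a Rubisco small subunit (Os12g0292400, -1.84 ± 0.39). Both were called in 7 of 16 leave-outs, and without the 14-day Black array they were at -0.84 and -0.92 and not called, while Os12g0292400 was at -2.76 without the 7-day one. Relative to its mean over all arrays, the Cy5 signal of the list had a median of 0.19 on the 7-day and -1.42 on the 14-day Black array. In the chlorophyll and carotenoid list 4 of 16 fell (6 adjusted over the list alone; adjusted p = 0.565 with an estimated correlation), among them the magnesium chelatase subunit Os07g0656500 (-0.92 ± 0.15). Heat-shock genes such as Os04g0445100 (-4.08 ± 0.73) fell in 5 of 120 cases (23 adjusted over the list alone, with 1 higher; adjusted p = 0.391 with an estimated correlation); the Koshihikari mean log2 intensity of Os04g0445100 on the Black arrays was 14.76. The histone and cell cycle list had 10 of 420 higher and 1 lower (10 and 0 adjusted over the list alone; adjusted p = 0.391 with an estimated correlation), but 319 of its 420 genes are cyclin-like F-box proteins, which mark proteins for degradation, and the 4 leading genes are of that kind.

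In all, 871 genes were called in Black, 379 higher and 492 lower. The count was 6 without the 14-day Black array, 329 without either BAB array, 261 without either Tokei-1284 array, and 358 or 277 without either array of an F1 (Black/Red or Red/Black). The reductase Os01g0633500 and the glucosyltransferase Os06g0192100 were called in all 16 leave-outs; the other pathway calls above were lost without the 14-day Black array, and those of Os02g0697400 (1.35 without that array) and Os03g0410000 in 7 and 12 leave-outs. The calls of Os07g0656500 and Os04g0445100 were lost in 1 and 3.

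**Figure D2:**
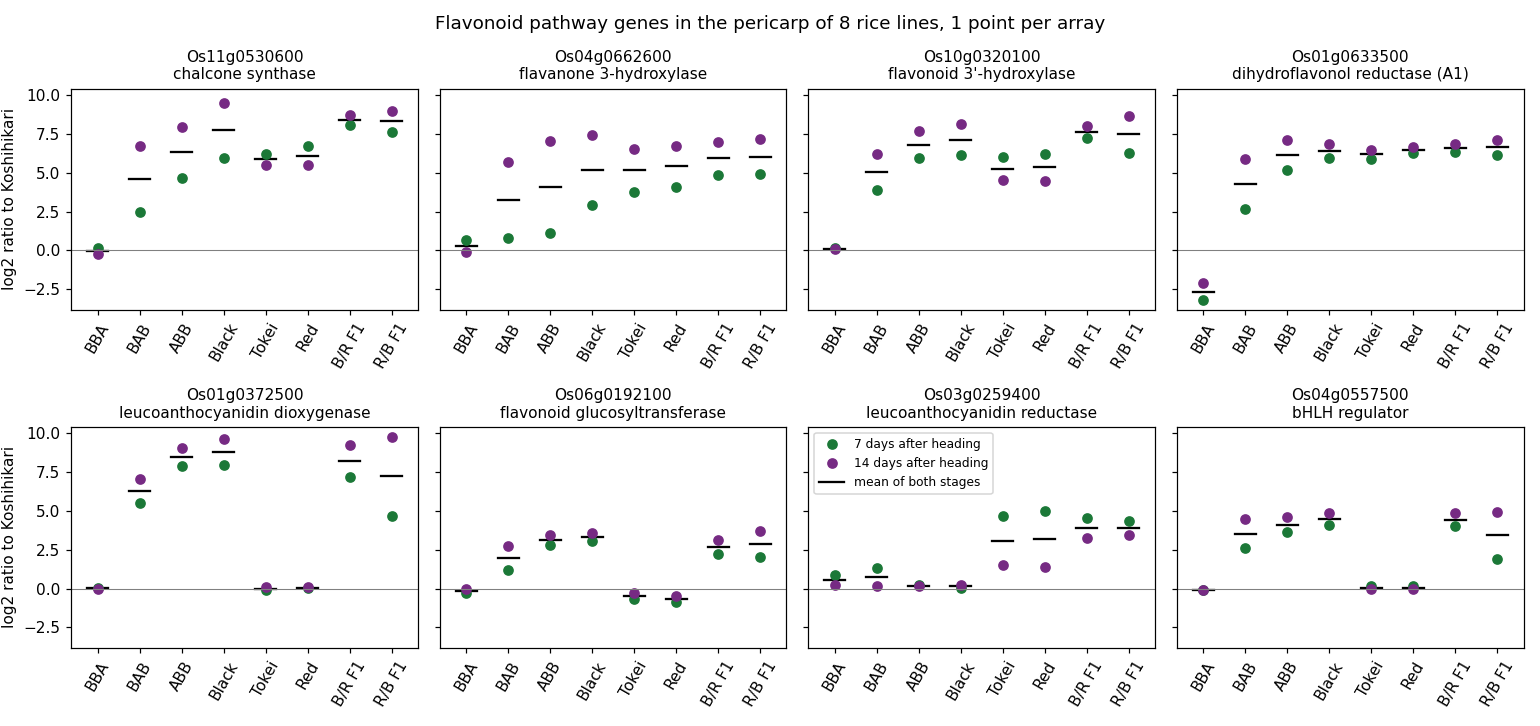
Log2 ratio of the line to Koshihikari for flavonoid pathway genes and the bHLH gene Os04g0557500 in each of the 8 lines, with 1 point per array, a colour per stage and a bar at the mean of both stages. Leucoanthocyanidin dioxygenase stands near 0 in BBA, Tokei-1284 and Red and at 6.27 to 8.83 in the other lines, while leucoanthocyanidin reductase (Os03g0259400) is raised in Tokei-1284, Red and both F1.

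In the ABB type NIL genes of the flavonoid pathway were raised too. Leucoanthocyanidin dioxygenase Os01g0372500 was 357-fold higher (8.48 ± 0.71, adjusted p = 0.000956), flavonoid 3'-monooxygenase Os10g0320100 111-fold, chalcone synthase Os11g0530600 79.3-fold (adjusted p = 0.0227) and reductase Os01g0633500 70.9-fold. The glucosyltransferase Os06g0192100 rose 8.84-fold, the bHLH gene Os04g0557500 17.5-fold (4.13 ± 0.48) and the glutathione S-transferase Os10g0395400, of a family that helps bring anthocyanins to the vacuole, 16.1-fold. Flavanone 3-hydroxylase Os04g0662600 was at 4.07 and did not pass (adjusted p = 0.163). Of the early flavonoid list 3 of 9 rose (7 adjusted over the list alone), of the late list 3 of 9 (5) and of the regulators 1 of 4 (3); each list's adjusted p was 0.168 with an estimated correlation. Falls included an RNase S-like gene (Os09g0538000, -3.05 ± 0.36) and a Bowman-Birk type proteinase inhibitor (Os01g0132000, -2.37 ± 0.27). There were 77 calls, 39 higher and 38 lower. The count was 302 without the 7-day ABB array and 24 without the 14-day one, and the calls of Os11g0530600, Os10g0320100, Os07g0214900 and Os04g0557500 were lost without the latter.

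The BAB type NIL also had raised pathway genes. Leucoanthocyanidin dioxygenase Os01g0372500 was at least 71.3-fold higher (6.27 ± 0.71, adjusted p = 0.00964), flavonoid 3'-monooxygenase Os10g0320100 32.9-fold, reductase Os01g0633500 19.3-fold and the glutathione S-transferase Os10g0395400 12.1-fold. The bHLH gene Os04g0557500 rose 11.6-fold and chalcone synthase Os07g0214900 3.74-fold; glucosyltransferase Os06g0192100 passed as well (adjusted p = 0.0137), whereas chalcone synthase Os11g0530600 (4.59, adjusted p = 0.108) and flavanone 3-hydroxylase Os04g0662600 (3.26, adjusted p = 0.191) did not pass. Called lower were the histone-fold gene Os01g0580400 (-3.18 ± 0.30), the calcium-binding EF-hand gene Os01g0579600 (-2.32 ± 0.24) and a vacuolar ATPase subunit (Os01g0587000, -1.51 ± 0.13). Of the early flavonoid list 2 of 9 rose (4 adjusted over the list alone), of the late list 3 of 9 (3) and of the regulators 1 of 4 (1), each with an adjusted p = 0.524 with an estimated correlation. No endosperm storage gene passed, while the list's median was -0.69 (camera adjusted p = 8.15e-09; adjusted p = 0.524 with an estimated correlation). In all 56 genes were called, 33 higher and 23 lower. The count was 5 and 14 without the 7-day and the 14-day BAB array and 262 without either ABB array. Only the call of reductase Os01g0633500 (2.68 at 7 and 5.86 at 14 days) was made in all 16 leave-outs, and that of Os10g0320100 was lost in 6.

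In the BBA type NIL the pigment pathway was not raised. The 14-day BBA array lay near the 7-day arrays (described below), so a later rise is not excluded. Leucoanthocyanidin dioxygenase Os01g0372500 (0.02), chalcone synthase Os11g0530600 (-0.03) and leucoanthocyanidin reductase Os03g0259400 (0.55) did not pass, and reductase Os01g0633500 was called lower (-2.65 ± 0.41, adjusted p = 0.0232; its second probe -1.30). No gene of the early flavonoid, regulator and flavone lists passed in limma, over all genes or adjusted over the list alone, among 4041 genes with an unadjusted p under 0.05. Also lower were the calcium-binding EF-hand gene Os01g0579600 (-4.20 ± 0.24, adjusted p = 0.000157), a lipid transfer domain gene (Os03g0369100, -2.60 ± 0.39) and the histone-fold gene Os01g0580400 (-2.40 ± 0.30). Called higher were an ethylene-responsive coactivator (Os06g0592500, 3.23 ± 0.49), a disease resistance response gene (Os03g0400200, 2.89 ± 0.43) and ubiquitin (Os09g0483400, 2.37 ± 0.30). The cell wall list had 1 of 141 higher (2 adjusted over the list alone), with a median of 0.11 (camera adjusted p = 0.00889; adjusted p = 0.932 with an estimated correlation). There were 178 calls, 79 higher and 99 lower. The count was 6 without the 7-day and 26 without the 14-day BBA array, 110, 106 and 102 without either array of BAB, Tokei-1284 and the Red/Black F1, and 329 without either ABB array; the call of Os01g0579600 was made in all 16 leave-outs, and the other named calls were lost without a BBA array.

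In the Red rice NIL early pathway genes, dihydroflavonol reductase and leucoanthocyanidin reductase were raised. Reductase Os01g0633500 was 89.6-fold higher (6.48 ± 0.41, adjusted p = 0.000168), chalcone synthase Os11g0530600 69.0-fold (6.11 ± 0.91, adjusted p = 0.00237), flavanone 3-hydroxylase Os04g0662600 42.9-fold and flavonoid 3'-monooxygenase Os10g0320100 40.6-fold. Leucoanthocyanidin reductase Os03g0259400, which makes the catechin units of proanthocyanidins, rose 9.25-fold (3.21 ± 0.58, adjusted p = 0.00537), with 5.004 at 7 days and 1.42 at 14 days; without the 7-day Red array it was at 1.91 and not called. The anthocyanidin reductases Os04g0630800 (0.08) and Os04g0630900 (0.21), of the same branch, did not pass. Leucoanthocyanidin dioxygenase Os01g0372500 (0.07, adjusted p = 0.956) did not pass. In the early flavonoid list 5 of 9 rose and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.706 with an estimated correlation); the fall, in the flavanone 3-hydroxylase-like Os03g0122300 (-0.90), was seen more weakly by its other probes (-0.40 and -0.35) and was at -0.58, not called, without the 7-day Red array. In the late list, which holds Os01g0633500 and Os03g0259400, 2 of 9 rose (3, with 1 lower, adjusted over the list alone), and it did not pass camera (adjusted p = 0.134). The C4H-like gene Os01g0820000 rose 2.02-fold.

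Outside the pathway, 45 of 120 heat-shock genes were higher and 12 lower in Red (51 and 14 adjusted over the list alone; camera adjusted p = 0.000784; adjusted p = 0.706 with an estimated correlation). HSP81-1 (Os04g0107900), a chaperone of the HSP90 family, reached 108-fold (6.75 ± 1.07) and the small heat-shock gene Os04g0445100 77.7-fold. These folds are against a Koshihikari that held the 8 genes described above at 9.58 to 10.49, lower than on the Black arrays (13.8 to 14.7) and the F1 arrays (14.0 to 14.2). Genes encoded close together on chromosome 7 fell, among them a prolamin (Os07g0219400, -5.83 ± 0.36, adjusted p = 0.000168), an alpha-amylase inhibitor (Os07g0213800, -5.52 ± 0.43) and a second prolamin (Os07g0219300, -5.11 ± 0.41). In the endosperm storage list 7 of 42 fell and 1 rose (6 and 1 adjusted over the list alone; adjusted p = 0.747 with an estimated correlation). Photosynthesis genes were higher in 12 of 60 cases and lower in 1 (12 and 1 adjusted over the list alone, adjusted p = 0.751 with an estimated correlation), led by the 22 kDa photosystem II protein (Os04g0690800, 2.87 ± 0.46). Relative to its mean over all arrays, the list had a median of 0.81 in Cy5 and -0.26 in Koshihikari on the 7-day Red array. On the 14-day one these were -0.46 and -0.37. Of 17 abscisic acid genes 6 rose (8, with 1 lower, adjusted over the list alone; adjusted p = 0.706 with an estimated correlation), among them zeaxanthin epoxidase (Os04g0448900, 1.19 ± 0.24), and of 48 peroxidase genes 9 rose (8 adjusted over the list alone; adjusted p = 0.706 with an estimated correlation). Ribosomal protein genes were lower in 106 of 302 cases and higher in 6 (133 and 9 adjusted over the list alone), with a median of -0.25 (adjusted p = 0.706 with an estimated correlation), but with median centring in place of loess this median was 0.29 and the direction of the peroxidase test turned too. There were 5902 calls, 3284 higher and 2618 lower. The count was 3098 without the 7-day and 1846 without the 14-day Red array; the calls of Os01g0633500, Os11g0530600, Os04g0662600, Os10g0320100 and the named chromosome 7 genes were made in all 16 leave-outs.

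**Figure D3:**
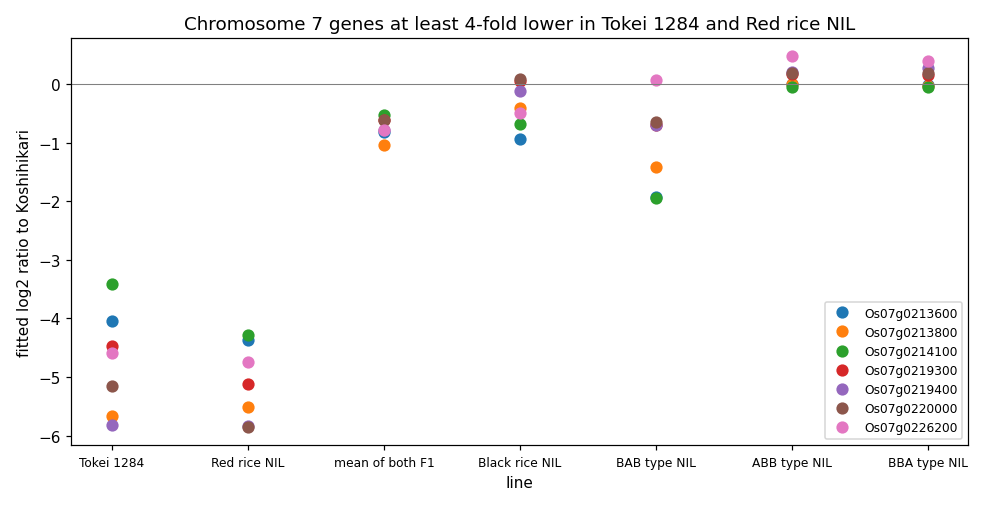
Fitted log2 ratio to Koshihikari (vertical axis) of the 7 chromosome 7 genes at least 4-fold lower in both Tokei-1284 and Red, 1 colour per gene, in 6 lines and the mean of both F1 (horizontal axis). They lie at -3.41 or below in Tokei-1284 and Red and at -1.04 to -0.53 in the mean of both F1.

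Tokei-1284, with the genotype Rc/rd, also had raised early pathway genes and raised dihydroflavonol reductase. Reductase Os01g0633500 was 73.3-fold higher (6.20 ± 0.41, adjusted p = 0.000386), chalcone synthase Os11g0530600 58.4-fold, flavonoid 3'-monooxygenase Os10g0320100 38.2-fold and flavanone 3-hydroxylase Os04g0662600 36.0-fold. Leucoanthocyanidin reductase Os03g0259400 rose 8.52-fold (3.09 ± 0.58, adjusted p = 0.0152), with 4.65 at 7 days and 1.53 at 14 days, and Os01g0372500 (adjusted p = 0.997) did not pass. The flavone branch gene Os10g0317900 (-1.24) and 4-coumarate-CoA ligase Os02g0177600 (-0.56) were lower. In the early flavonoid list 4 of 9 rose (5, with 1 lower, adjusted over the list alone; adjusted p = 0.602 with an estimated correlation), and in the late list 2 of 9 (3), which did not pass camera (adjusted p = 0.103). Against the same low Koshihikari level as for Red, HSP81-1 (Os04g0107900) was 66.8-fold higher; 37 of 120 heat-shock genes rose and 2 fell (43 and 12 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). The prolamin Os07g0219400 (-5.81 ± 0.36), the alpha-amylase inhibitor Os07g0213800 (-5.67 ± 0.43) and nicotianamine synthase (Os03g0307200, -3.47 ± 0.85), an enzyme of iron transport, fell. Of 10 genes at least 4-fold lower in both Tokei-1284 and Red 7 lie close together on chromosome 7, including Os07g0220000 and Os07g0226200, which were chosen after their values were seen; in the test of windows of 25 genes no window passed in either line. There were 2335 calls, 1525 higher and 810 lower. The count was 6 without the 7-day and 111 without the 14-day Tokei-1284 array; the calls of Os01g0633500, Os07g0219400 and Os07g0213800 were made in all 16 leave-outs, and the other named calls were lost without a Tokei-1284 array. Without the 7-day one Os03g0259400 was at 2.06, Os10g0317900 at -0.74 and Os02g0177600 at -0.35.

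Both reciprocal F1 raised leucoanthocyanidin dioxygenase and leucoanthocyanidin reductase together. Chalcone synthase Os11g0530600 was 335-fold higher in the Black/Red F1 and 318-fold in the Red/Black F1, leucoanthocyanidin dioxygenase Os01g0372500 298-fold (8.22 ± 0.71, adjusted p = 0.00201) and 151-fold (7.24 ± 0.71, adjusted p = 0.00548), and leucoanthocyanidin reductase Os03g0259400 14.7-fold (3.87 ± 0.58, adjusted p = 0.017) and 15.0-fold (3.91 ± 0.58, adjusted p = 0.0266). Reductase Os01g0633500 rose 96.2-fold and 99.1-fold, glucosyltransferase Os06g0192100 6.46-fold and 7.33-fold, and the bHLH gene Os04g0557500 21.8-fold and 10.8-fold (2.23 in the Red/Black F1 without its 14-day array, not called). In the Red/Black F1 the log2 ratio of Os01g0372500 was 4.71 at 7 days and 9.77 at 14 days. The early flavonoid list had 5 and 4 of 9 higher (7 and 7 adjusted over the list alone) and the late list 4 and 4 of 9 (4 and 4), with adjusted p of 0.311 and 0.303 with an estimated correlation for both lists. In the Black/Red F1 also 3 of 26 embryo and aleurone genes rose (13 adjusted over the list alone; adjusted p = 0.341 with an estimated correlation), among them an oleosin (Os04g0546500, 1.57 ± 0.22), a coat protein of oil bodies. In the same F1 4 of 100 genes of the pathogenesis-related list rose (4 adjusted over the list alone, adjusted p = 0.527 with an estimated correlation), led by a chitinase (Os11g0700900, 2.34 ± 0.52, but 1.53 without the 7-day Black/Red array, not called). Of the 100, 33 are genes with an ERF domain, which are transcription factors. With median centring in place of loess the direction of this list's test turned.

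The Black/Red F1 had 957 calls (403 higher, 554 lower) and the Red/Black F1 244 (120 and 124). For the first, the count was 0 and 11 without its own 7-day and 14-day array, 598, 629 and 433 without either array of BBA, BAB and Tokei-1284, and 558 without either Red/Black array. For the second it was 77 and 0 without its own arrays, 159, 96 and 73 without either array of BBA, BAB and Tokei-1284, and 108 without either Black/Red array. None of the named pathway calls of an F1 was made in all 16 leave-outs, since each was lost without 1 or both arrays of that F1. With the F1 arrays alone, fitted as 1 scan day, 34 and 25 genes were called.

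Other lists passed camera against Koshihikari. In Tokei-1284 3 of 17 abscisic acid genes rose (3 adjusted over the list alone), 4 of 52 glutathione S-transferases rose (4) and 1 of 10 lignin genes fell (1), the hydroxycinnamoyl transferase Os02g0611800 (-0.58 ± 0.13), each with an adjusted p = 0.602 with an estimated correlation. In the chlorophyll and carotenoid list 5 of 16 rose in Red (5 adjusted over the list alone; adjusted p = 0.747 with an estimated correlation), among them a beta-carotene hydroxylase (Os03g0125100). In the Black/Red F1 5 of 128 UDP-glycosyltransferases rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.311 with an estimated correlation), led by Os03g0841600 (2.90 ± 0.35), and 1 of 29 lipid transfer and cuticle genes rose (4; adjusted p = 0.482 with an estimated correlation). Ribosomal protein genes had medians of -0.14 in Tokei-1284, -0.11 in ABB, -0.13 in the Black/Red F1 and -0.11 in the Red/Black F1, but of 0.32, 0.30, 0.21 and 0.22 with median centring. In Tokei-1284 30 of 302 ribosomal protein genes were lower and 1 higher (40 and 1 adjusted over the list alone; adjusted p = 0.602 with an estimated correlation). Photosynthesis genes in the Red/Black F1 had a median of -0.21, but 0.17 with median centring. Starch genes had medians of -0.28 in BAB and -0.18 in ABB, but 0.21 and 0.41 with median centring.

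Black against Red tests where the pigment types part. In the ratio, leucoanthocyanidin dioxygenase Os01g0372500 was higher in Black by 8.76 ± 1.001 (adjusted p = 0.00138), the bHLH gene Os04g0557500 by 4.43 ± 0.68 (adjusted p = 0.00307) and glucosyltransferase Os06g0192100 by 4.01 ± 0.33 (adjusted p = 0.00104). The first 2 lay at background in Red, and in Cy5 intensity Black was at least 987-fold and at least 42.2-fold higher. Leucoanthocyanidin reductase Os03g0259400 was lower in Black (-3.07 ± 0.83, adjusted p = 0.0275; -1.77 without the 7-day Red array, not called). Reductase Os01g0633500 did not differ past the threshold (-0.10 ± 0.57, adjusted p = 0.921). Also higher in Black were 4-coumarate-CoA ligase Os02g0697400 (3.88 ± 0.73), the MYB gene Os03g0410000 (1.11 ± 0.21) and the WD40 gene Os02g0682500 (1.77 ± 0.54; 1.11 without the 14-day Red array, not called), and the C4H-like Os01g0820000 was lower (-1.02 ± 0.18). In the fit of Cy5 alone the differences were 10.08, 5.51, 6.09 and -3.75 for the first 4 genes, all past the threshold. There Os02g0697400 (4.44) and Os01g0820000 (-0.93) passed too, while Os03g0410000 (1.28, adjusted p = 0.051) and Os02g0682500 (1.80, adjusted p = 0.0817) did not.

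Across lists, 41 of 60 photosynthesis genes were lower in Black than in Red and 1 higher (45 and 2 adjusted over the list alone), with a median of -1.23 (camera adjusted p = 8.23e-14; adjusted p = 0.545 with an estimated correlation); the 22 kDa photosystem II protein Os04g0690800 was at -4.07 ± 0.64. The 41 had a median of -1.47 in the ratio and -0.987 in Cy5 alone, where 3 of them passed. Of the 16 chlorophyll and carotenoid genes 9 were lower (9 adjusted over the list alone), and of 17 abscisic acid genes 8 (8, with 1 higher), each with an adjusted p = 0.545 with an estimated correlation; in Cy5 alone these 9 and 8 had medians of -0.614 and -0.794, beside -1.19 and -1.01 in the ratio. Heat-shock genes were lower in 48 of 120 cases and higher in 9 (52 and 13 adjusted over the list alone; adjusted p = 0.545 with an estimated correlation); HSP81-1 (Os04g0107900) was at -10.57 ± 1.51, and in Cy5 alone at -6.43 (adjusted p = 0.0734). Over the 48 genes the median difference was -3.86 in the ratio and -1.96 in Cy5 alone, between arrays whose Koshihikari levels of such genes also differed. Ribosomal protein genes were higher in 111 of 302 cases and lower in 20 (129 and 24 adjusted over the list alone; adjusted p = 0.545 with an estimated correlation), led by the 40S protein S9 (Os03g0379500, 1.42 ± 0.32). Most of this difference was absent in Cy5 alone: the 111 had a median of 0.638 in the ratio and 0.217 in Cy5, where 97 had the same sign and 2 passed. The endosperm storage list had 5 of 42 higher and 1 lower (4 and 1 adjusted over the list alone; adjusted p = 0.918 with an estimated correlation), with the prolamin Os07g0219400 at 5.70 ± 0.50 (4.95 in Cy5). The early flavonoid list (1 of 9 higher, 0 adjusted over the list alone; camera adjusted p = 0.562) and the late list (2 higher and 1 lower of 9, 2 and 2 adjusted over the list alone; camera adjusted p = 0.682) did not pass as lists.

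The other lists did not pass camera between Black and Red. Over all genes, 3 of 4 pigment regulators were higher (3, with 1 lower, adjusted over the list alone; camera adjusted p = 0.145), and in the phenylpropanoid core 1 of 18 was higher and 1 lower (1 and 1; 0.417). Of the flavone and flavonol branch 0 of 4 passed (0; 0.211), of the lignin branch 1 was higher and 1 lower of 10 (1 and 1; 0.996), and of the shikimate list 1 and 2 of 26 (0 and 2; 0.838). Higher and lower numbered 4 and 7 of 52 glutathione S-transferases (4 and 7; 0.996), 2 and 3 of 33 MATE transporters (2 and 3; 0.632), 7 and 16 of 128 UDP-glycosyltransferases (6 and 15; 0.58) and 1 and 7 of 48 peroxidases (1 and 7; 0.196). For laccases they were 1 and 0 of 19 (0 and 0; 0.876), for starch synthesis 0 and 0 of 9 (0 and 0; 0.828), for embryo and aleurone 0 and 3 of 26 (0 and 0; 0.0675) and for jasmonate 5 and 5 of 35 (6 and 7; 0.97). The pathogenesis-related list had 5 and 11 of 100 (0 and 7; 0.333), the histone and cell cycle list 48 and 48 of 420 (48 and 48; 0.329) and the cell wall list 5 and 20 of 141 (5 and 16; 0.406). Lipid transfer and cuticle genes gave 0 and 5 of 29 (0 and 4; 0.632), sugar transport genes 2 and 14 of 63 (2 and 14; 0.114), MYB factors 8 and 23 of 134 (16 and 26; 0.37) and bHLH factors 4 and 8 of 99 (4 and 8; 0.8). In each pair of brackets the counts are those adjusted over the list alone.

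There were 5485 calls, 2540 higher and 2945 lower, and 1609 without the 14-day Black and 2853 without the 14-day Red array. In Cy5 alone 1406 genes were called, 1153 of them also called in the ratio with the same sign. The lines lay on different slides and scan days, so slide and line cannot be told apart.

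Red against Tokei-1284, on 1 slide, compares Rc/Rd with Rc/rd, where Rd is the locus of dihydroflavonol reductase. The transcript of reductase Os01g0633500 was at 6.48 in Red and 6.20 in Tokei-1284. One gene passed, the hypothetical protein Os01g0685000 (-3.04, adjusted p = 0.00862), named after its value was seen; 1178 genes had an unadjusted p under 0.05 in limma. No photosynthesis gene passed, while the list's median was 0.35 (camera adjusted p = 9.18e-07; adjusted p = 0.663 with an estimated correlation). The count was 0 without either Tokei-1284 array, 5 and 9 without the 7-day and the 14-day Red array, 2 without either ABB array and 5 without either Red/Black F1 array.

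BBA against Black compared a line without raised pigment genes with one that has them. In BBA reductase Os01g0633500 was lower by -9.04 ± 0.57 (adjusted p = 0.000867), chalcone synthase Os11g0530600 by -7.78 ± 1.28 (adjusted p = 0.0458), flavonoid 3'-monooxygenase Os10g0320100 by -7.04 ± 1.01 (adjusted p = 0.0369) and chalcone synthase Os07g0214900 by -2.64 ± 0.32. Leucoanthocyanidin dioxygenase Os01g0372500 was at -8.81 (adjusted p = 0.0188) and the bHLH gene Os04g0557500 at -4.58 (adjusted p = 0.0419); both lay at background in BBA, at least 1015-fold and at least 45.8-fold lower in Cy5 intensity. Glucosyltransferase Os06g0192100 was at -3.50 ± 0.33 and glutathione S-transferase Os10g0395400 at -3.72 ± 0.46. The Cy5 differences of these genes had the same sign and passed too. Heat-shock genes did not do so: Os04g0445100 was higher in BBA by 7.40 in the ratio and at -0.09 in Cy5, and of 120 such genes 35 were higher and 4 lower adjusted over the list alone (4 higher over all genes; adjusted p = 0.48 with an estimated correlation), while the 35 had a median of 3.22 in the ratio and 0.0938 in Cy5. In the early flavonoid list 3 of 9 were lower (4 adjusted over the list alone; adjusted p = 0.48 with an estimated correlation).

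Between BBA and Black, Cy5 alone gave 4416 calls, 43 of them shared with the ratio with the same sign. These Cy5 calls are open to a difference of stage, since the 14-day BBA array lay near the 7-day arrays (described below). The ratio differences are open to it as well, since log2 ratios of pathway genes in Black changed with stage. Chalcone synthase Os11g0530600 was at 5.96 at 7 and 9.52 at 14 days in Black. At 7 days it was at 0.17 in BBA, so this gene was lower in BBA at that stage already. The ratio gave 100 calls (52 higher, 48 lower), of which 73 had the same sign in Cy5. Without 1 array the count was 10 and 5 (BBA, 7 and 14 days), 489 and 2 (Black, 7 and 14 days), 25, 610, 19 and 48 (either array of BAB, ABB, Tokei-1284 and Red) and 22 and 34 (either array of the Black/Red and the Red/Black F1). Only the call of Os01g0633500 was made in all 16 leave-outs, and that of Os11g0530600 in 3.

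BAB against Black gave 94 calls, 77 higher and 17 lower. The acetylornithine aminotransferase Os07g0461900, an enzyme of arginine synthesis, was lower in BAB (-2.94 ± 0.35, adjusted p = 0.0317), as was the uncharacterised Os01g0625900 (-3.71 ± 0.39); in Cy5 alone they were at -1.91 and -2.86 and did not pass. Named rises included heat-shock genes such as Os04g0445100 (8.08 ± 1.03; 3.65 in Cy5, adjusted p = 0.452), and 6 of 120 heat-shock genes passed (31, with 1 lower, adjusted over the list alone; adjusted p = 0.72 with an estimated correlation). No pathway gene passed, and leucoanthocyanidin dioxygenase Os01g0372500 was at -2.55 (adjusted p = 0.257). No named call was made in more than 7 of the 16 leave-outs: the count was 0 without any 1 array of BBA, BAB or the Red/Black F1, or the 14-day Black array, 211 without the 7-day Black array, 463 without either ABB array, and 1, 45 and 7 without either array of Tokei-1284, Red and the Black/Red F1. In Cy5 alone 9 genes were called.

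ABB against Black gave 23 calls, 12 higher and 11 lower. Calcineurin B-like protein 8 (Os03g0448500), a calcium sensor, was lower in ABB, where it lay at background (-2.61 ± 0.37, adjusted p = 0.0489; at least 4.54-fold in Cy5 intensity), and Os03g0572300, annotated as a modifier of rudimentary, fell by 1.26 (± 0.14, adjusted p = 0.0216). The DnaJ heat-shock gene Os01g0606900 was 32.1-fold higher in the ratio (adjusted p = 0.0298), but at 2.19 in Cy5 alone (adjusted p = 0.65). It was the 1 of 120 heat-shock genes that passed (30 adjusted over the list alone; camera adjusted p = 0.00115; adjusted p = 0.759 with an estimated correlation), and the 30 had a median of 3.73 in the ratio and 0.861 in Cy5. The vacuolar ATPase subunit Os01g0587000 was higher (1.32 ± 0.18), as was the mRNA-binding gene Os01g0603000 (1.33 ± 0.14). All 23 had the same sign in Cy5. The count was 712 and 11 without the 7-day and the 14-day ABB array, 48 and 3 without those of Black, and 10, 8, 6 and 7 without either array of BBA, BAB, Tokei-1284 and the Black/Red F1. None of the named calls was made in all 16 leave-outs, and that of Os03g0448500 in 1.

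BAB against ABB, on 1 slide, gave 19 calls, 14 higher and 5 lower. The histone-fold gene Os01g0580400 was lower in BAB (-3.09 ± 0.42, adjusted p = 0.0442), as were the vacuolar ATPase subunit Os01g0587000 (-1.47 ± 0.18) and the mRNA-binding gene Os01g0603000 (-1.12 ± 0.14); Os03g0572300 was higher (1.29 ± 0.14), as was the autophagy gene Os03g0391000 (0.84 ± 0.11). No pathway gene passed, and no named call was made in more than 9 of the 16 leave-outs. The count was 2 and 1 without a BAB array (7 and 14 days), 3 and 48 without an ABB array, 6, 7, 8 and 11 without either array of BBA, Tokei-1284, the Black/Red and the Red/Black F1, and 0 with the arrays of that scan day alone.

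The mean of both F1 against the mean of their parents gave 0 calls in limma, with 3799 genes at an unadjusted p under 0.05; leaving out a BBA array, the 7-day Black array or the 14-day Black/Red array gave 1, a Red array 2 and the 7-day Red/Black array 12. Leucoanthocyanidin reductase Os03g0259400 was at 2.22 (adjusted p = 0.164) and leucoanthocyanidin dioxygenase Os01g0372500 at 3.28 (adjusted p = 0.128). In Cy5 alone both passed (3.01 and 3.22). Each of these genes was called higher against Koshihikari in only 1 of the parents. The parents' value is a mean of log2 values, so an F1 midway between the parents in intensity would also lie above it. In the late flavonoid list 3 of 9 were higher adjusted over the list alone (adjusted p = 0.612 with an estimated correlation). In Cy5 alone 2323 genes were called, and 0 of them in the ratio, with r of 0.216 between both differences across genes. The F1 lay on another slide and scan day than either parent. The Cy5 differences between F1 and parents thus cannot be told from a difference of slide or scan day. The Black/Red against the Red/Black F1 gave 0 calls, with 458 at an unadjusted p under 0.05 (1 without the 14-day Black/Red and 11 without the 7-day Red/Black array). Embryo and aleurone genes had a median of 0.48 between them (camera adjusted p = 6.34e-12; adjusted p = 0.293 with an estimated correlation), though none of 26 passed, over all genes or adjusted over the list alone.

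Between lines, other lists passed camera with few or no genes past the threshold over all genes. Photosynthesis genes were higher than in Black, with list medians of 0.72 in BBA, 0.92 in BAB and 0.78 in ABB. None of 60 passed over all genes, and 31 (with 1 lower), 44 and 35 did adjusted over the list alone (adjusted p = 0.48, 0.72 and 0.78 with an estimated correlation). In Cy5 alone these had medians of 1.4999, 0.625 and 0.621. The BBA value is open to a difference of stage, since the 14-day BBA array lay near the 7-day arrays (described below). Relative to its mean over all arrays, Cy5 of the list had medians of 0.62 and 0.34 on the BBA and 0.19 and -1.42 on the Black arrays (7 and 14 days). In BAB against Black the early flavonoid list had a median of -1.09 (adjusted p = 0.749 with an estimated correlation), and against ABB one of -0.81 (adjusted p = 0.582 with an estimated correlation). Endosperm storage genes had medians of -0.59 in Red against Tokei-1284, -0.66 in BAB against ABB, 0.53 in the F1 against the parents and 0.42 between the F1 (adjusted p = 0.663, 0.582, 0.612 and 0.801 with an estimated correlation).

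From 7 to 14 days photosynthesis and ribosomal protein genes fell in the lines, and embryo and endosperm genes rose. Whether the 14-day samples held more embryo or endosperm was not tested. Embryonic abundant protein 1 (Os01g0159600) rose 77.9-fold (6.28 ± 0.64, adjusted p = 0.000108, 2.21 to 8.71 in the 8 lines; Koshihikari mean 4.20), a glucanase (Os01g0942300) 50.8-fold and an oxalate oxidase (Os08g0189300) 42.7-fold. Embryo and aleurone genes rose in 20 of 26 cases (20 adjusted over the list alone), endosperm storage genes in 30 of 42 (31) and starch genes in 5 of 9 with 1 lower (5 and 1), for example the LEA gene Os06g0110200 (4.62 ± 0.53), the seed allergen Os07g0214100 (3.81 ± 0.30) and an ADP-glucose pyrophosphorylase subunit (Os08g0345800, 1.88 ± 0.19). Photosynthesis genes fell in 47 of 60 cases and rose in 3 (49 and 3 adjusted over the list alone), and chlorophyll genes fell in 11 of 16 (12), among them protochlorophyllide reductase (Os04g0678700, -2.25 ± 0.23). Ribosomal protein genes fell in 252 of 302 cases and rose in 4 (261 and 4). Cell wall genes fell in 68 of 141 and rose in 21 (71 and 21), with a pectinesterase (Os02g0783000) at -3.80 ± 0.35. In the histone and cell cycle list 152 of 420 fell and 64 rose (152 and 64), with histone H2A (Os03g0279200) at -3.28 ± 0.33 and histone H4 (Os04g0583600) at -3.24 ± 0.43. These lists passed camera, with an adjusted p of 0.374 with an estimated correlation, but 0.398 for starch and 0.43 for the histone list.

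Phenylpropanoid core genes also rose, 11 of 18 (12 adjusted over the list alone), as did 11 of 17 abscisic acid genes (11), 14 of 35 jasmonate genes with 5 lower (15 and 6), 42 of 100 in the pathogenesis-related list with 15 lower (43 and 15), 23 of 52 glutathione S-transferases with 11 lower (24 and 11) and 46 of 128 UDP-glycosyltransferases with 13 lower (45 and 13), each with an adjusted p = 0.374 with an estimated correlation. Examples are a ZIM domain gene of jasmonate signalling (Os03g0180900, 3.95 ± 0.38) and a class III chitinase (Os10g0416800, 3.71 ± 0.19). The early flavonoid list (1 of 9 higher, 0 adjusted over the list alone; camera adjusted p = 0.145) did not pass. In all 13046 genes were called, 5814 higher and 7232 lower, of which 2961 changed more than 2-fold. The named changes kept the call without any 1 of the 8 lines. The 14-day BBA array lay near the 7-day arrays: on a scale from 0 for the 7-day mean to 1 for the 14-day mean of the other lines, its line RNA was at 0.145 and its Koshihikari at 0.102, against 0.844 to 1.18 and 0.755 to 1.11 on the other 14-day arrays.

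**Figure D4:**
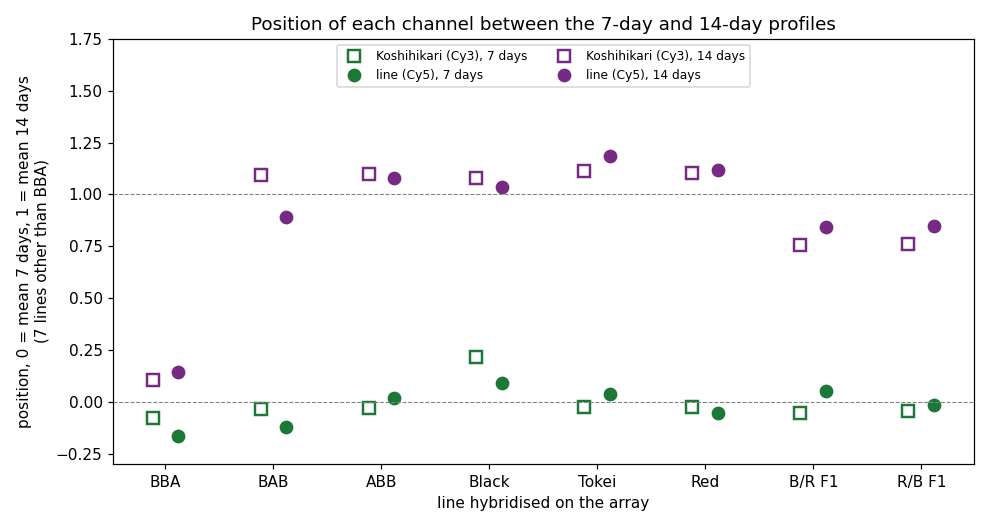
Position of each array (vertical axis, without units) from the mean of the 7-day arrays (0) to that of the 14-day arrays (1) of the 7 lines other than BBA, by line (horizontal axis), with squares for Koshihikari and circles for the line. Both channels of the 14-day BBA array, at 0.102 and 0.145, lie beside the 7-day arrays.

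In the ratio to Koshihikari 418 genes changed with stage (164 higher, 254 lower), and without 1 line the count was 0 (BAB, Tokei-1284, Red or the Red/Black F1), 2 (Black), 7 (ABB) or 1095 (BBA); without line as block it was 54.

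Called genes lay together on chromosomes 1, 3 and 4. Whether probes in these stretches detect alleles of a donor parent poorly was not tested. This limit also applies to the genes named above that lie there. With 1003 windows of 25 genes in each comparison, 26 passed over all comparisons, where a window counts once per comparison in which it passed. BBA had 5, the first 3 on chromosome 1 (Os01g0572200 to Os01g0591300) and the others on chromosome 3 (Os03g0384800 to Os03g0397400); in the strongest 7 of 25 genes were lower (adjusted p = 3.36e-07). BAB had 3, on chromosomes 1 and 4, ABB 5, on chromosomes 3 and 4, Black 9, of which 8 on chromosome 1 and 1 on chromosome 3, and the Black/Red F1 1 on chromosome 1. Tokei-1284, Red and the Red/Black F1 had 0. With windows of 10 genes 10 passed and with windows of 50 genes 33, of which 1 in Tokei-1284.

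**Figure D5:**
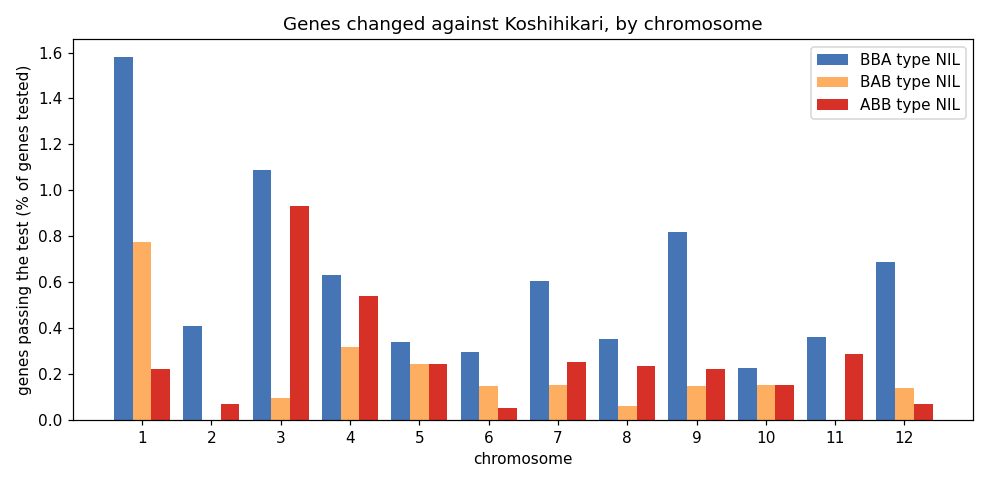
Percent of the tested genes that passed the test against Koshihikari (vertical axis) on each chromosome (horizontal axis), with a bar each for BBA, BAB and ABB. BBA is highest on chromosomes 1 (1.58%) and 3 (1.09%), BAB on chromosome 1 (0.776%) and ABB on chromosomes 3 (0.934%) and 4 (0.541%).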

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

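The tests of the BBA slide, of heat-shock and photosynthesis genes and of chromosome 7 were chosen after the results were seen. Of 46 groups of 8 lines, 7 held a line far from the others, by Dixon's criterion for the gap to the nearest line, and chance gives about 1 in 20 groups.

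In 5 of the 7 groups the line was BBA. Its change from 7 to 14 days was -0.97 for Os07g0106900, against -7.20 to -4.58 in the other lines, -0.68 for Os10g0150700, -1.62 for the subtilisin gene Os03g0430500 and -1.40 for the peroxidase Os02g0833900. Koshihikari on the BBA slide changed with a slope of 0.183 against the mean stage change, and with 0.746 to 1.15 on the other slides. Slower ripening of BBA alone would leave that Koshihikari slope within the range of the others, so it is excluded as the whole cause. The spike-in slope of the 14-day BBA array, of observed on expected log ratios between the dyes, was 0.942 of the mean of the others. Both BBA arrays (0.836 and 0.839) lay below all others (0.873 to 0.913). Strong compression of ratios is thus not seen, but the slope does not test compression within a channel between arrays, so compressed signals are not excluded. RNA from grains nearer the 7-day stage may explain it, since Koshihikari of the 14-day BBA array lay at 0.102 between the mean 7-day (0) and 14-day (1) profiles. A mislabelled or repeated 7-day sample was not tested apart from this.

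Heat-shock genes were far lower in Black than in Red and higher in BBA than in Black. A Koshihikari RNA that differs between scan days could be the whole cause in BBA against Black, where the median Cy5 difference of 35 genes was 0.0938 (quartiles -0.47 and 0.75) beside 3.22 in the ratio. Between Black and Red, the median of 48 genes in Cy5 was -1.96 (lower quartile -3.56), all 48 had the same sign and 17 passed. These 48 were picked by the ratio, which contains Cy5, so their choice favours a negative Cy5 difference. Over the whole heat-shock list, Cy5 relative to its mean over all arrays had medians of -0.188 and -0.115 in Black (7 and 14 days). In Red they were 0.0853 and 0.338. Koshihikari as the whole cause is thus left open for the heat-shock list. For photosynthesis, 41 genes picked in the same way had a median of -0.987 in Cy5, all of the same sign. Over that whole list the Cy5 medians were 0.19 and -1.42 in Black and 0.81 and -0.46 in Red (7 and 14 days). They were lower in Black at both stages, which argues against Koshihikari as the whole cause for that list between Black and Red. This holds only as far as Koshihikari does not enter the Cy5 values through the normalization. A normalization of Cy5 by itself was not run for differences between lines. A difference between the lines and a difference of scan day or handling cannot be told apart there, since Black lay alone on its slide and scan day.

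Genes of chromosome 7 from Os07g0213600 to Os07g0226200 were far lower in Tokei-1284 and Red. Less endosperm in those samples is excluded as the whole cause, since 35 endosperm storage genes elsewhere had a median of -0.444 in Red (quartiles -0.926 and -0.243). A donor segment whose alleles the probes detect poorly stays open. The F1, with a copy from each parent, had a median of -0.784 (-1.04 to -0.53), within the range set for it. The medians of BAB (-0.705) and Black (-0.408), for which no such segment was set, lay there too. The F1 median thus does not single it out. By gene, Black ran from -0.94 to 0.087 and BAB from -1.95 to 0.066. In BAB the whole endosperm storage list was lower as well. The titles give Tokei-1284 and Red the allele Rc, whose locus (Os07g0211500) precedes this stretch in the order of IDs. Lower expression of the donor alleles would look the same and was not tested.

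The MATE transporter list had a median stage change of 0.784 in Black, against -0.0285 to 0.301 in the other lines. The endosperm storage list had 1.52 in Red, against 0.194 to 0.822.

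By the test of the difference itself, Black and Red differed in Os03g0122300 (1.37), Os01g0372500 (8.76), Os03g0259400 (-3.07), Os06g0192100 (4.01), Os04g0557500 (4.43), Os03g0410000 (1.11) and Os02g0682500 (1.77). For Os03g0122300 the other probes had -0.47 and -0.43 in Black, so that difference rests on 1 probe. BBA and Black differed in Os11g0530600 (-7.78), Os07g0214900 (-2.64), Os10g0320100 (-7.04), Os01g0633500 (-9.04), Os01g0372500 (-8.81), Os06g0192100 (-3.50) and Os04g0557500 (-4.58).

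Of the values of the 1020 spots for microRNA precursors, which no comparison used, 13.7% were well above background in both channels, against 1.31% for 153 negative controls.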

How the results depend on the processing

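The alternatives with Cy5 alone, without both BBA arrays and with 1 scan day were chosen after the results were seen. Slide as a random block was planned but gave no values, because each slide holds whole lines. The spread between slides cannot be told from the lines, and it is not in the errors of differences between lines on different slides. Of 9098 values of named genes under all alternatives, 7011 kept call and direction, 2073 lost the call and 14 turned direction; of 585 values of lists, 394 kept both, 177 lost the call and 14 turned. Where a count moved, the cause was not tested.

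Without background subtraction the counts were 1481 (Black/Red F1), 2187 (Red/Black F1), 7 (Red against Tokei-1284), 52 (BAB against Black) and 59 (F1 against parents). The scanner log ratios gave 315 in BBA, 571 in Black, 329 and 815 in the Black/Red and Red/Black F1, 26 for Red against Tokei-1284, 157, 3 and 36 for BBA, BAB and ABB against Black, 29 for BAB against ABB and 10 for F1 against parents. The values of the authors gave 312 in BBA, 342 and 756 in the F1, 25, 157, 3, 35, 29 and 10 in the same order of differences. Without the stage term there were 187 in Black, 287 and 44 in the F1, 62 for BBA and 50 for BAB against Black.

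Median centring gave 8491 in BBA, 9966 in BAB, 8932 in ABB, 12425 in Black, 9856 in Tokei-1284, 11375 in Red, 4491 and 2531 in the F1, 66 for BBA and 13 for BAB against Black, and 2653 for stage in the ratio. It held 165 of the 178 calls in BBA and 673 of the 871 in Black. It turned Os07g0139600 in the Red/Black F1 (0.11) and list directions. The list medians were then 0.21 for starch and 0.24 for embryo and aleurone in BAB, -0.22 for peroxidases, 0.41 for starch and 0.30 for ribosomal proteins in ABB, -0.17 for peroxidases and 0.32 for ribosomal proteins in Tokei-1284, and 0.00408 and 0.29 for these in Red. In the Black/Red F1 they were 0.0354 for the pathogenesis-related list and 0.21 for ribosomal proteins, and in the Red/Black F1 0.0225 for peroxidases, 0.17 for photosynthesis and 0.22 for ribosomal proteins. The mean over probes turned Os03g0385900 in ABB (-0.47).

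Each line minus the mean of the other 7 gave 37 in BBA, 0 in BAB, 23 in ABB, 2600 in Black, 29 in Tokei-1284, 1920 in Red and 0 in each F1. It asks another question, since most lines raise the pathway. It turned Os07g0214900 (-0.55), Os10g0320100 (-0.63) and Os01g0633500 (-0.84) in BAB, Os11g0530600 (-0.0487) and Os10g0320100 (-0.38) in Tokei-1284, Os10g0320100 (-0.29) in Red and Os01g0579600 (0.27) in the Red/Black F1.

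Cy5 alone gave 1406 for Black against Red, 3 for Red against Tokei-1284, 4416 for BBA and 9 for BAB against Black, 32 for BAB against ABB, 2323 for F1 against parents and 4828 between the 8 lines. It turned Os04g0445100 (-0.0887), Os01g0136200 (-1.12), Os03g0245800 (-0.0698), Os08g0546800 (-0.16) and Os01g0170000 (-0.84) in BBA against Black. Without both BBA arrays the counts were 598 and 159 in the F1, 0 and 10 for BAB and ABB against Black, 6 for BAB against ABB and 1 for F1 against parents. Scan day 2 alone gave 7 in BAB, 17 in ABB, 25 in Tokei-1284, 3906 in Red, and 0 for Red against Tokei-1284 and BAB against ABB. Scan day 4 alone gave 34 and 25 in the F1.

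Leaving out each array in turn gave 6 to 329 in BBA, 5 to 262 in BAB, 24 to 302 in ABB, 6 to 1181 in Black, 6 to 2626 in Tokei-1284, 1846 to 6016 in Red, 0 to 1087 in the Black/Red and 0 to 334 in the Red/Black F1. For differences it gave 1609 to 5497 for Black against Red, 0 to 9 for Red against Tokei-1284, 2 to 610, 0 to 463 and 3 to 712 for BBA, BAB and ABB against Black, 1 to 48 for BAB against ABB, 0 to 12 for F1 against parents, 0 to 11 between the F1 and 164 to 1648 between the 8 lines. For stage in the ratio, leaving out a line gave 0 to 1095, with 7 without ABB and 2 without Black, and no line block 54. With an estimated correlation 0 of 117 list calls held, and with windows of 10 and of 50 genes 10 and 33 passed in place of 26, each window counted once per comparison. Windows of 50 also gave 1 in Tokei-1284 and 1 for BAB against Black, where windows of 25 gave 0.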

Other observations

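Some of the largest changes lay outside the pigment pathway. The calcium-binding EF-hand gene Os01g0579600 was lower in BBA (-4.20) and BAB (-2.32). The histone-fold gene Os01g0580400 was lower in both (-2.40 and -3.18), and neither was called in ABB. Both lie in a window of chromosome 1 (Os01g0572200 to Os01g0580400) where every called gene was lower. These numbered 7 in BBA, 3 in BAB and 6 in Black. Whether the probes there detect donor alleles poorly was not tested. The zinc-finger gene Os01g0612700, of a family that restrains cell death, was lower in Black (-2.63), Red (-2.56) and the Black/Red F1 (-3.56), as well as in BBA, BAB and the Red/Black F1.

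The test of the letters in the line names and the reversal of whole scan days were chosen after the results were seen; the reversal of stage within lines was not. Whether the letters stand for donor segments on chromosomes 1, 3 and 4 in that order, with B for the donor of Black and A for Koshihikari, is left open. The order was read from where these calls cluster, so the counts below restate that clustering and are no independent test of it. Of the genes called in exactly 2 of BBA, BAB and ABB that lie on these chromosomes, 30 of 32 were on the chromosome that this order gives the pair: 18 of 18 for BBA and BAB on chromosome 1, 7 of 8 for BBA and ABB on chromosome 3, and 5 of 6 for BAB and ABB on chromosome 4. A further 11 shared genes lay elsewhere. The bHLH gene Os04g0557500, on chromosome 4, was raised in BAB and ABB and not in BBA. The labels do not give the letters' meaning.

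Chance can be excluded for the change with stage in Cy5, with each line's RNA taken as a separate sample: of 100 sign patterns that reverse stage within lines, 1 called as many genes, the labelled stages. These called 13046, and the highest other pattern 10304. In the ratio the lines of a scan day share their Koshihikari RNA, so whole scan days were reversed. The 8 such patterns are too few for a share under 0.05; the labelled stages called 418 genes and the highest other pattern 175. The highest other pattern reversed BBA alone in both, so the BBA arrays carry little of the stage change.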
